A study of Sus scrofa with 6 samples.

How the data were processed

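Nuclei of pig kidney were profiled by droplet single-nucleus RNA-seq with a 3′ chemistry of 10x Genomics, in which each captured RNA molecule carries a unique molecular identifier (UMI). The labels put 3 libraries in the group with induced chronic kidney disease (CKD) and 3 in the Normal group, and the series text says that the nuclei came from female pigs. The labels name the tissue as kidney and the cell type as renal arteries. The clusters held nuclei of the glomerulus, most tubule segments, the collecting duct, vessels, fibroblasts and immune cells, though none was named thin limb or myeloid. The values were therefore read as those of whole kidney. Each library was taken as 1 pig. Replicate numbers were given in accession order and pair nothing.

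The deposited values are UMI counts per gene and barcode, whole numbers with no normalization, in 1 matrix per library. Reads were aligned and counted with Cell Ranger 7.1.0 against Sscrofa11.1, per the submitters' processing notes. The annotation release and whether intronic reads were counted are not given in the sources used here. The matrices hold 51816 barcodes and 35670 features. Of the features, 17511 carry a symbol in the deposited matrices and 17734 after matching to a table of gene names. Features without a symbol are given by their Ensembl identifier. Coordinates come from the RefSeq table of the same assembly, which lists TAFA2 under its older symbol FAM19A2.

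Nuclei with at least 300 genes, at least 500 UMIs and at most 10% of UMIs from the 13 mitochondrion-encoded genes were kept. Doublets were scored per library with Scrublet, run through scanpy 1.11.5. Its automatic threshold called 0 doublets in Normal 1, so in each library the nuclei with the highest scores were removed, at 0.8% per 1000 barcodes, which took out 5.10% to 8.84% per library. This left 47852 nuclei. Counts were scaled to 10000 per nucleus and logged. The 3000 most variable genes, 40 principal components, 20 neighbours and Leiden clustering at resolution 1 with seed 1 gave 42 clusters. No batch integration was applied, so clusters can follow single libraries.

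Clusters were named from marker lists of 24 cell types. A cluster took the type with the highest mean fold of its markers over the median cluster, with 10 CPM added to both. At least 3 markers had to reach a 2-fold excess and be seen in 5% of the cluster's nuclei. A cluster stayed unnamed where markers of another class outnumbered its own among its 10 leading genes, where its depth was very low and none of its markers led it, or where its median doublet score was above 0.2. The last threshold was set after the scores were seen and kept out cluster 38, at a mean of 0.0404% of CKD and 0.191% of Normal nuclei, cluster 39, at 0.172% and 0.0370%, and cluster 40, with 43 nuclei of which 90.7% were of CKD 3. Connecting tubule and principal cell clusters formed 1 class, and the single cluster led by markers of injured proximal tubule was counted in the proximal tubule. Class names stand for nuclei that resemble the type by these markers. No cluster was named after myeloid, B or plasma, mast, neutrophil, urothelial, Schwann, adipocyte, erythroid or thin limb markers. Cluster 32, which had 10 of 14 myeloid markers but was led by genes of several immune types, was tested under its number.

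Raw counts were summed per library over all nuclei and per class, where each of the 6 libraries had at least 20 nuclei of the class. The sums were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test with TMM factors and filterByExpr, and Benjamini-Hochberg adjustment within the class at 0.05. Folds are CKD over Normal on the log2 scale with their standard error, and levels of genes are CPM per library by edgeR, a count scaled to the total of the genes that passed the filter times the TMM factor. Levels of Y-linked genes and of KDM6A, those in the plot of TAFA2 and ADAM12 by class, and shares of marker RNA were scaled to all UMIs. Gene lists, 27 in all, were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over 297 combinations of list and class. Camera with an estimated correlation and fry, a test of whether the genes of a list move one way on balance, were run beside it. A list needed 5 measured members. The difference in effect between proximal tubule and thick ascending limb was tested as an interaction, with the library as a block. Shares of nuclei and depth were compared by a two-sided exact permutation test over libraries, which cannot give a p below 0.1 with 3 against 3.

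The marker lists, gene lists, tests and the rule for named genes were fixed before the data were examined. The rule took genes with a symbol, an adjusted p under 0.05, a mean log2 CPM of at least 4 and no overlap between groups, up to 10 in each direction in all nuclei and in the proximal tubule and up to 3 in each direction in the other classes. Where none passed, the pair of genes with the lowest p was taken among those with that mean level and no overlap between groups, given as values. It added the 4 members with the lowest p of each list that was called, and a set of sentinel genes of kidney injury, transport and lipid metabolism. Of these, the ones that bear on a comparison are named here. Some genes that the rule took are not reported here.

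The edgeR, camera and interaction steps were tested on simulated counts drawn from the means and library sizes of these data. In the proximal tubule, 5.80% of 2-fold, 55.7% of 4-fold and 98.6% of 16-fold changes were recovered. The figures were 8.75%, 68.5% and 98.5% in the sum of all nuclei, and 23.5%, 79.3% and 100% in the distal convoluted tubule. Of the genes called in these simulations, 9.32% in the proximal tubule, 5.22% in all nuclei, 6.67% in the distal convoluted tubule and 8.55% in the T or NK lymphocyte class had not been changed. Of 12 lists shifted by 0.5 on the log2 scale 11 were recovered. The simulated genes varied independently of each other, so these simulations did not measure false calls of lists with correlated genes. The interaction test recovered 67.5% of 4-fold differences, with 9 false calls.

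The alternatives planned were DESeq2 1.42.0, RLE size factors, no filter on low counts, sums thinned to equal depth, equal numbers of nuclei, doublets kept, at least 800 genes, at most 2% mitochondrion-encoded UMIs, classes by marker score, Leiden resolution 2, injured proximal tubule left out, adjustment over all classes, genes 10 times higher in another class left out, other denominators, and each library left out in turn. Added after the data were seen were Scrublet's automatic calls, leaving out CKD 2 and Normal 1 together, Leiden seed 2, and the interaction tests of the proximal tubule with the podocyte and the distal convoluted tubule. CKD 2 was chosen for its Y-linked counts and Normal 1 for its low depth. Seed 2, which gave 41 clusters, was added because the borders of clusters shifted with the numerical settings of the processor; these settings were then fixed, and the values given are those with them fixed. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and leidenalg 0.10.2 were used.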

Results

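The study compared kidneys of pigs with induced chronic kidney disease (CKD) against kidneys of age-matched pigs on standard chow (Normal). CKD had been induced at 14 weeks of age by narrowing of both renal arteries together with a diet rich in cholesterol and carbohydrate, and lasted 14 weeks. Gene expression was measured in single nuclei of 3 pigs per group, 1 library per pig. After filtering, the CKD libraries held 6384, 9145 and 8211 nuclei and the Normal libraries 8039, 10048 and 6025. Total UMI counts were 3.89e+07, 5.04e+07 and 4.48e+07 in CKD and 2.19e+07, 4.76e+07 and 3.15e+07 in Normal. The CKD libraries were deeper per nucleus, with a median of 5035 ± 454 UMIs against 3444 ± 1358 (SD, n = 3 per group; exact permutation p = 0.1, the smallest possible). Normal 1 was the shallowest, at a median of 1878 UMIs. The median share of mitochondrion-encoded UMIs was 0.267 ± 0.180% in CKD and 0.255 ± 0.108% in Normal (SD, n = 3; exact permutation p = 1). CKD 2 carried RNA of Y-linked genes, at 108 CPM of ZFY against at most 0.983 CPM in the other libraries, although the series describes the pigs as female.

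The first comparison asked whether CKD changed the cell makeup of the kidney. Nuclei resembling the proximal tubule, the reabsorbing segment behind the glomerulus, made up 55.4 ± 3.00% of CKD and 56.8 ± 2.40% of Normal nuclei (SD, n = 3 per group; exact permutation p = 0.6). Intercalated cells, the acid-base regulating cells of the collecting duct, held 5.51 ± 1.12% of CKD against 4.11 ± 0.514% of Normal nuclei, and every CKD library lay above every Normal one (exact permutation p = 0.1, the smallest possible). An edgeR test of the nucleus counts gave them an adjusted p of 0.815 at a log2 fold of 0.42. The thick ascending limb held 8.21 ± 0.750% against 9.44 ± 0.625% (exact permutation p = 0.2). Connecting tubule or principal cells held 10.0 ± 2.69% against 9.02 ± 1.16% (exact permutation p = 0.8), and the distal convoluted tubule 3.13 ± 0.403% against 3.42 ± 0.427% (p = 0.5). Endothelium held 7.22 ± 0.820% against 6.82 ± 0.874% (exact permutation p = 0.7) and fibroblasts 2.30 ± 0.245% against 2.15 ± 0.575% (p = 0.9). Mural cells, the contractile cells of vessel walls, held 0.774 ± 0.311% against 0.680 ± 0.177% (exact permutation p = 0.7). Podocytes, the filter cells of the glomerulus, held 1.502 ± 0.242% against 1.83 ± 0.704% (exact permutation p = 0.5), and the parietal epithelium that lines its capsule 1.56 ± 0.242% against 1.53 ± 0.171% (p = 0.9). T or NK lymphocytes held 1.27 ± 0.824% against 1.08 ± 0.471% (exact permutation p = 0.8) and the immune cluster 32 0.656 ± 0.287% against 0.686 ± 0.262% (p = 0.9). Lymphatic endothelium held 0.177 ± 0.0273% against 0.148 ± 0.0722% (exact permutation p = 0.6) and cycling cells 0.175 ± 0.123% against 0.255 ± 0.238% (p = 0.7). Unnamed clusters other than 32 and 36 held 1.79 ± 0.415% against 1.97 ± 0.608% (exact permutation p = 0.8). Shares follow the yield of nuclei as well as the tissue, and the groups differed in depth.

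**Figure D1:**
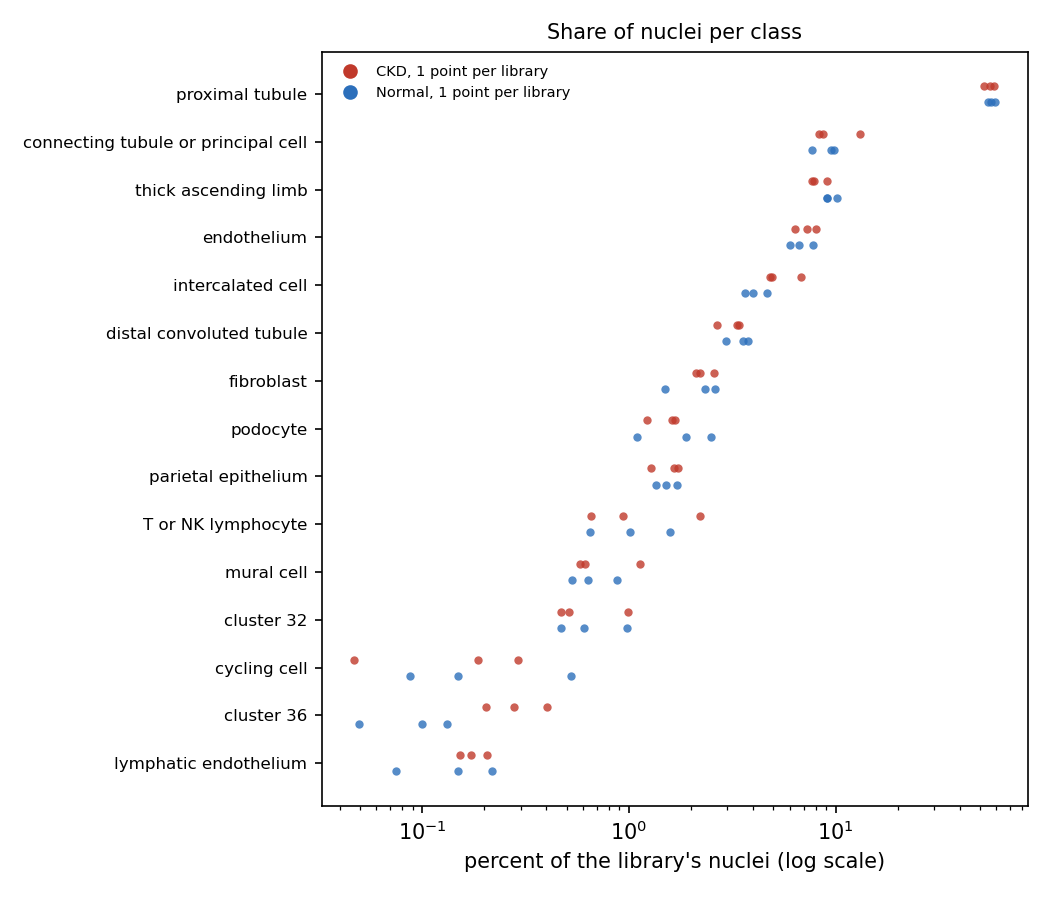
Share of nuclei per class, in percent of each library's nuclei on a log scale, with 1 point per library and the 2 groups in separate colours. The proximal tubule lies between 52.1% and 59.3% in all 6 libraries, and intercalated cells lie between 4.79% and 6.80% in CKD against 3.65% to 4.66% in Normal.

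The second comparison asked which genes differed between CKD and Normal kidneys in the sum of all nuclei. TAFA2, which encodes a secreted protein related to chemokines, fell by 4.28 ± 0.40 on the log2 scale (SE, n = 3 per group; edgeR adjusted p = 0.0317), from 74.5, 119 and 45.0 CPM in Normal to 4.62, 4.69 and 2.92 CPM in CKD. SNAP25, a protein of vesicle fusion chosen here after its values were seen, rose by 2.24 ± 0.21 (adjusted p = 0.0317), from 4.12, 5.06 and 5.46 CPM to 20.2, 27.5 and 21.7 CPM. In intercalated cells SNAP25 stood at 344, 318 and 432 CPM in CKD against 46.3, 105 and 84.5 CPM in Normal, a log2 fold of 2.19 ± 0.30 with an adjusted p of 0.252. The unnamed gene ENSSSCG00000035347 rose by 4.85 ± 0.52 (adjusted p = 0.0437), and ENSSSCG00000062268 fell by 4.73 ± 0.38 (adjusted p = 0.0317). The levels of both did not overlap between the 3 CKD and 3 Normal libraries. TAFA2 lies on chromosome 5 at 26391969 to 26893517 and SNAP25 on chromosome 17 at 19096115 to 19227580 of Sscrofa11.1. FN1, the matrix protein fibronectin, had a log2 fold of −1.15 ± 0.28 that did not pass (adjusted p = 0.66), with every CKD library below every Normal one.

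In all, edgeR called 10 of 22659 genes in the sum of all nuclei, 2 higher and 8 lower in CKD, with 1491 genes at an unadjusted p under 0.05. DESeq2 called 116, 64 of them higher. The levels of 12.5% of genes did not overlap between the groups, where chance gives 10%. EdgeR called 0 genes without CKD 1, CKD 2, CKD 3 or Normal 3, with 1038, 1120, 1337 and 1052 genes at an unadjusted p under 0.05, and 18 without Normal 1. It called 1 with CKD 2 and Normal 1 both left out. The adjusted p of TAFA2 was 0.175, 0.234 and 0.190 without CKD 1, 2 or 3 and 0.0686 without Normal 3, within a range of 2.83e-24 to 0.234 over its alternatives. That of SNAP25 was 0.175, 0.234 and 0.190 without CKD 1, 2 or 3, 0.0881 without Normal 2 and 0.206 without Normal 3, within 7.21e-16 to 0.234.

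The third comparison asked the same within each class. In the proximal tubule TAFA2 was nearly absent from CKD kidneys, at 1.32, 0.498 and 0.854 CPM against 99.1, 182 and 66.6 CPM in Normal, and fell by 7.03 ± 0.55 on the log2 scale (SE, n = 3 per group; edgeR adjusted p = 0.00923). A run of 5 unnamed genes, 245 to 251 positions from TAFA2 in the order of the annotation, also fell, led by ENSSSCG00000062268 with a fall of 7.60 ± 0.50 (adjusted p = 0.00923). ENSSSCG00000035347 rose by 5.05 ± 0.47 (adjusted p = 0.0207), from 6.04, 2.34 and 2.73 CPM to 116, 78.7 and 168 CPM. UMOD, which encodes uromodulin, and SLC8A1, a sodium-calcium exchanger, had log2 folds of −0.61 ± 0.16 and −1.63 ± 0.38 that did not pass (adjusted p = 0.544 for each), with every CKD library below every Normal one. UMOD is a marker of the thick ascending limb and SLC8A1 of the connecting tubule. RNA of those segments as the source of these counts was not tested. The 7 calls, 1 higher and 6 lower, came from 19388 genes, of which 1504 had an unadjusted p under 0.05 and DESeq2 called 125. Of the DESeq2 calls 69 were higher and 56 lower in CKD. The levels of 14.6% of genes did not overlap between groups, against 10% by chance.

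Most proximal tubule nuclei of each CKD pig lay in other clusters than those of Normal, and than those of the other CKD pigs. Clusters 2, 5, 6, 12, 14 and 23 held mainly CKD nuclei, each with at least 97.2% from 1 library. Clusters 0, 1, 4, 9 and 18 held mainly Normal nuclei, and cluster 0 had 97.1% from Normal 1. In all, 8 of the 14 clusters, with 59.1% of the nuclei, came to over 80% from 1 library. Without CKD 1, CKD 2 or CKD 3 edgeR called 0 genes in the proximal tubule, with 1113, 1157 and 1216 at an unadjusted p under 0.05, while 16 were called without Normal 1 and 3 without Normal 3. With CKD 2 and Normal 1 both left out 1 gene was called. The adjusted p of TAFA2 was then 0.0977. It was 0.0640, 0.0869 and 0.131 without CKD 1, 2 or 3, within a range of 5.16e-44 to 0.131 over the 22 alternatives, of which 18 kept it past the threshold.

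In the distal convoluted tubule ADAM12, a membrane metalloprotease, fell by 6.02 ± 0.47 on the log2 scale (SE, n = 3 per group; edgeR adjusted p = 0.000676), from 174, 438 and 260 CPM in Normal to 6.05, 1.68 and 6.65 CPM in CKD. It passed under all 21 alternatives, with adjusted p values from 3.08e-68 to 0.0302. ADAM12 lies on chromosome 14 at 135302188 to 135682144 of Sscrofa11.1. The unnamed ENSSSCG00000047889 rose by 4.13 ± 0.46 (adjusted p = 0.0123; higher in 3 of 3 CKD libraries), and with a second unnamed gene made up the 3 calls among 10339 genes. Of these genes 573 had an unadjusted p under 0.05 and DESeq2 called 19. The count was 1 without CKD 1, CKD 2, CKD 3 or Normal 3, 7 without Normal 2, and 6 with CKD 2 and Normal 1 both left out.

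In the T or NK lymphocyte class SRD5A2, a steroid 5-alpha reductase, fell by 3.70 ± 0.49 on the log2 scale (SE, n = 3 per group; edgeR adjusted p = 0.036), from 24.8, 102 and 78.6 CPM in Normal to 4.68, 8.44 and 4.92 CPM in CKD. ENSSSCG00000035347 rose here too, by 5.63 ± 0.66 (adjusted p = 0.0203; higher in 3 of 3 CKD libraries). This class carried much proximal tubule RNA, with 1.61 ± 0.162% of its CKD and 1.12 ± 0.382% of its Normal UMIs from markers of that segment (SD, n = 3; exact permutation p = 0.1, the smallest possible), and a median of 6264 UMIs per nucleus. The proximal tubule itself had 2.34 ± 0.155% and 2.22 ± 0.171% (SD, n = 3; exact permutation p = 0.5). There SRD5A2 stood at 1.80, 3.52 and 9.74 CPM in CKD against 4.16, 134 and 97.9 CPM in Normal (log2 fold −3.97 ± 1.15, adjusted p = 0.562). Of 8075 genes 2 were called, 474 had an unadjusted p under 0.05 and DESeq2 called 15. The adjusted p of SRD5A2 was 0.0962, 0.0834 and 0.173 without CKD 1, 2 or 3, 0.265 without Normal 2 and 0.193 without Normal 3, within 3.83e-11 to 0.265 over its alternatives. In this class the count was 0 without CKD 1, Normal 2 or Normal 3, with 421, 823 and 459 genes at an unadjusted p under 0.05 in edgeR, and 1 without CKD 2. No cluster was named T or NK lymphocyte at Leiden resolution 2 or with Leiden seed 2.

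**Figure D2:**
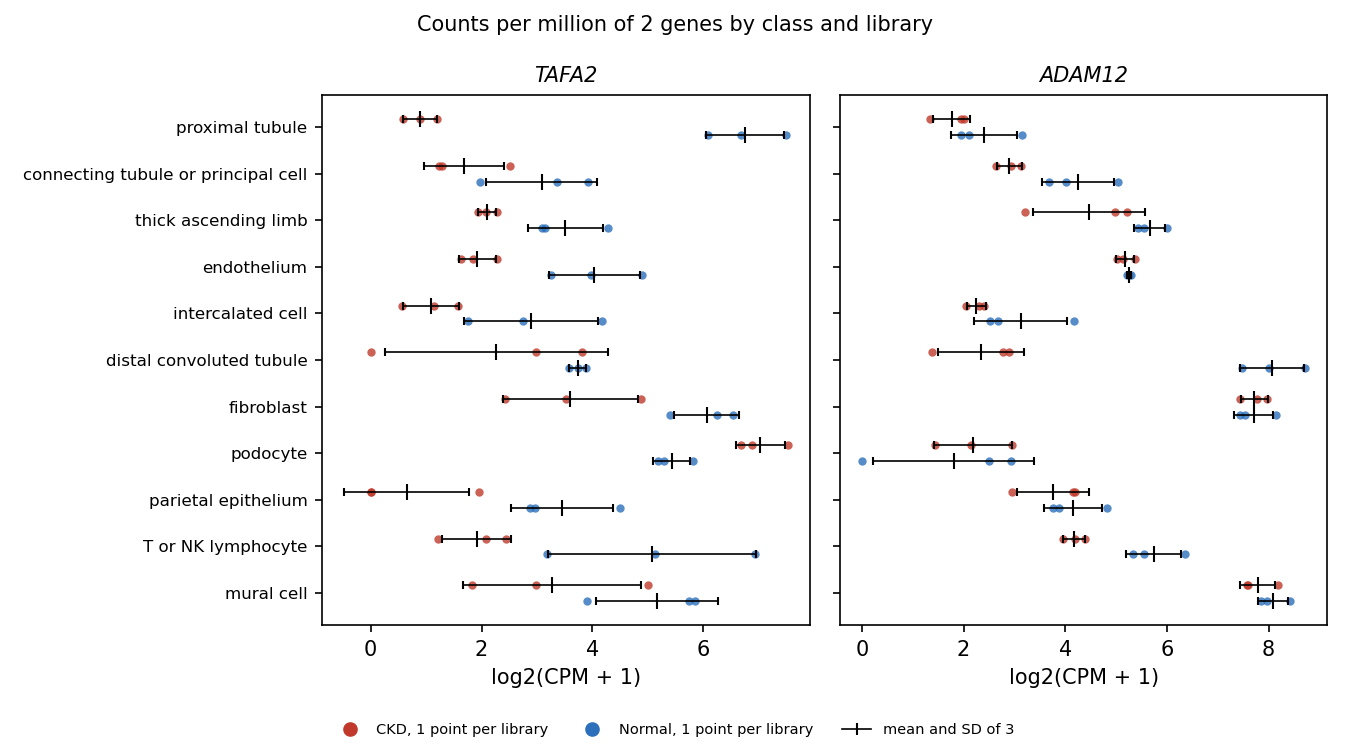
Level of TAFA2 and ADAM12 as log2(CPM + 1) by class, with 1 point per library and the mean and SD of each group; CPM is here scaled to all UMIs of the class, without normalization factors. On this scale TAFA2 lies between 0.499 and 1.30 CPM in CKD and between 66.6 and 179 CPM in Normal in the proximal tubule, and ADAM12 between 1.59 and 6.42 CPM in CKD and between 176 and 421 CPM in Normal in the distal convoluted tubule.

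In the other classes no gene passed, and genes of the pair with the lowest p in each are given as values. The thick ascending limb had ADGRG6, an adhesion G protein-coupled receptor, at 46.2, 50.4 and 36.5 CPM in CKD against 13.4, 8.60 and 10.8 CPM in Normal (log2 fold 2.04 ± 0.26, edgeR adjusted p = 0.363). It also had PTGS2, the inducible cyclooxygenase, at 29.6, 17.1 and 34.8 CPM against 7.04, 5.93 and 7.77 CPM (1.97 ± 0.33, adjusted p = 0.603). The endothelium had LAMA3, a laminin chain, at a log2 fold of 1.78 ± 0.23 (adjusted p = 0.16) and MYO7A, an unconventional myosin, at −1.26 ± 0.22 (adjusted p = 0.626). Connecting tubule or principal cells had SLC16A12 at −1.04 ± 0.16 and TNNI3K at 1.59 ± 0.26, both with an adjusted p of 0.234. Intercalated cells had PECR, a peroxisomal reductase of fatty acid elongation, at −1.55 ± 0.26 (adjusted p = 0.486) beside SNAP25. Fibroblasts had the calcium channel TRPC6 at 2.23 ± 0.40, at an adjusted p of 0.309. Podocytes had TMEM178B at −1.56 ± 0.27 and TAFA2, here higher in each CKD library, at 1.61 ± 0.28, both at 0.486. Mural cells had PLPP4 at −3.44 ± 0.61 and DCDC2 at −2.05 ± 0.38, both at 0.334. Parietal epithelium had BBOX1 at −1.76 ± 0.34 and the sodium channel subunit SCNN1B at 1.62 ± 0.29, both at 0.363. Cluster 32 had PLEK at −2.44 ± 0.41 and CYP2C42 at 2.74 ± 0.48, both at 0.18. Each of these genes lay wholly above or below in CKD, in 3 of 3 libraries, because only such genes were taken. Of all genes tested, the share without overlap ran from 8.69% in mural cells to 12.5% in podocytes, against 10% by chance.

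In these 9 classes edgeR called 0 genes. The unadjusted p was under 0.05 for 544 of 13449 genes in the thick ascending limb, 658 of 10624 in the endothelium, 720 of 13350 in connecting tubule or principal cells and 680 of 11462 in intercalated cells, where DESeq2 called 12, 12, 44 and 29. It was under 0.05 for 279 genes in fibroblasts, 480 in podocytes, 126 in mural cells, 304 in parietal epithelium and 328 in cluster 32, where DESeq2 called 2, 3, 0, 0 and 2. Leaving out 1 library gave 3 calls in intercalated cells without Normal 1, and 1 call each in podocytes and in cluster 32 without CKD 2 and in the thick ascending limb without Normal 2.

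The fourth comparison asked whether genes of 1 pathway moved together. Camera called 65 of 297 combinations of list and class, 42 higher and 23 lower in CKD. With an estimated correlation 0 were called, with 12 at an unadjusted p under 0.05 and a lowest adjusted p of 0.729. Fry called 0, with 34 at an unadjusted p under 0.05 and a lowest adjusted p of 0.182. Of the 65 calls, 26 held with each of the 6 libraries left out in turn. The mean level of the list lay beyond every Normal library in all 3 CKD libraries for 24 of the 65, where chance gives 10% for lists not chosen by their call. In 3 calls 1 CKD library lay on the opposite side of every Normal one. Camera called 30 combinations with CKD 2 and Normal 1 both left out. In the other splits of the 6 libraries into 3 and 3 it called between 33 and 67.

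Genes induced by interferons were higher in CKD in 9 of the 11 classes tested. In the thick ascending limb 30 of 30 measured members were higher, with a median log2 fold of 0.91 (camera adjusted p = 1.41e-13). In the endothelium 32 of 32 were higher, with a median of 0.89 (adjusted p = 1.82e-13). The median was 0.96 in connecting tubule or principal cells, with 25 of 27 members higher (adjusted p = 2.71e-12), and 1.11 in the distal convoluted tubule, with 20 of 21 (5.06e-07). It was 0.79 in fibroblasts, with 17 of 18 (3.34e-07), 0.64 in podocytes, with 20 of 20 (0.000531), and 0.59 in parietal epithelium, with 10 of 10 (0.000865). The proximal tubule (median 0.46, 29 of 34 members, adjusted p = 0.00494) and intercalated cells (0.36, 14 of 20, 0.0222) were also called. All 9 calls were lost with an estimated correlation, at adjusted p = 0.729 with an estimated correlation in 7 classes and 0.799 in podocytes and the proximal tubule. Adjusted over the list alone, 10 members rose in connecting tubule or principal cells, 10 in the distal convoluted tubule, 8 in the endothelium, 2 in fibroblasts and 1 in parietal epithelium. OAS2, an activator of RNA decay in infected cells, stood at 582, 453 and 210 CPM in CKD endothelium against 58.3, 113 and 185 CPM, a log2 fold of 1.81 ± 0.45. MX1, an antiviral GTPase, had a log2 fold of 2.57 ± 0.62 in the distal convoluted tubule, at 104, 184 and 24.7 CPM against 13.6, 9.98 and 29.0 CPM. The transcription factor IRF9 had 1.34 ± 0.35 in the thick ascending limb and 1.81 ± 0.55 in the proximal tubule, and RSAD2, or viperin, 1.86 ± 0.48 in the endothelium. None of these 4 passed over all genes. Markers of immune cells had median log2 folds of 0.41 in parietal epithelium (2 measured), 0.31 in intercalated cells (4), 0.23 in podocytes (3), 0.16 in fibroblasts (2) and 0.12 in the distal convoluted tubule (3). They had −0.45 in the thick ascending limb (8) and in connecting tubule or principal cells (7), −0.25 in the endothelium (4) and −0.13 in the proximal tubule (21).

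The interferon genes stood high in CKD 1 and CKD 2 alone. In the endothelium the mean level of the list lay 1.36 and 1.18 above the Normal mean on the log2 scale in these libraries and 0.14 in CKD 3, among the Normal libraries, and in each of the 9 classes 2 of 3 CKD libraries lay above every Normal one. In the proximal tubule CKD 3 lay below every Normal library. The call held in 6 classes whichever library was left out. It was lost in podocytes without CKD 2 (adjusted p = 0.0968) or Normal 1 (0.0845), in the proximal tubule without CKD 2 (0.514) or Normal 1 (0.0581), and in intercalated cells without CKD 2 (0.319), Normal 1 (0.0631) or Normal 3 (0.0744) or at equal depth (0.123). It was also lost in fibroblasts (0.0728) and parietal epithelium (0.117) with CKD 2 and Normal 1 both left out.

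**Figure D3:**
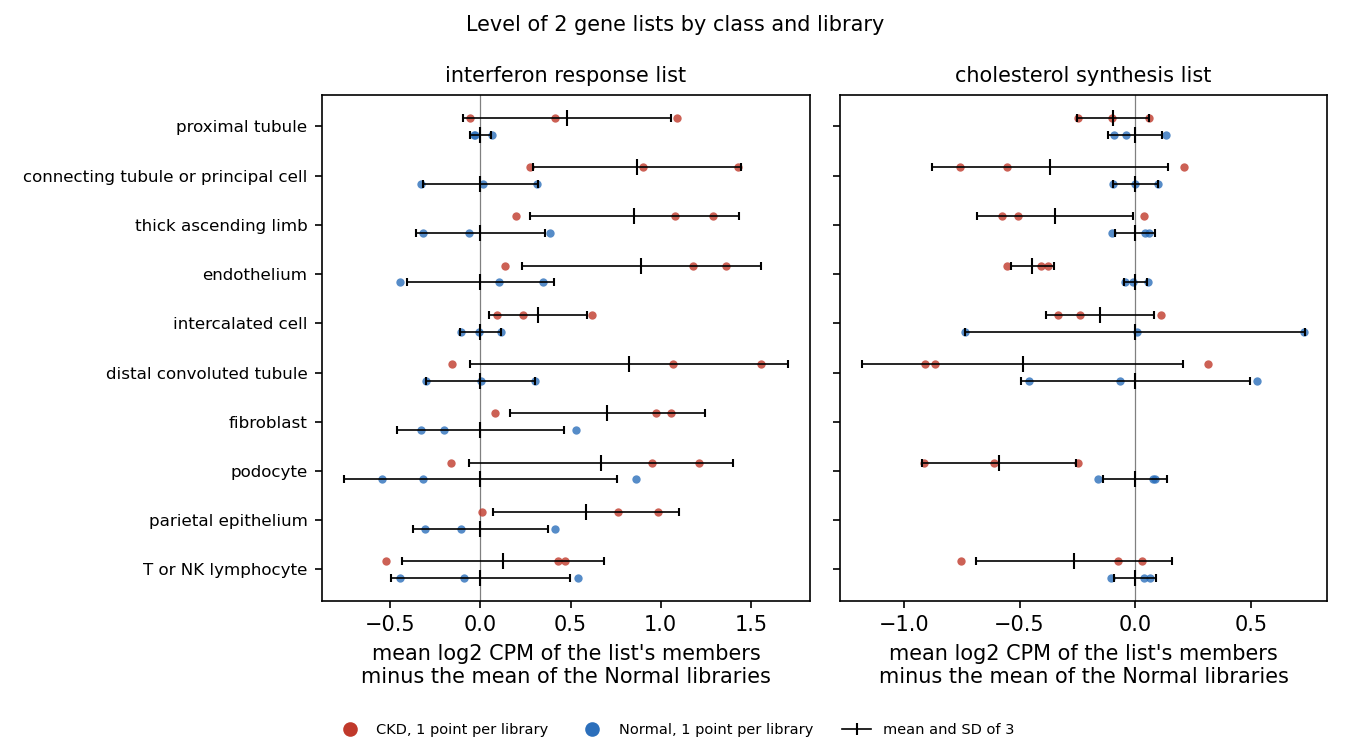
Mean log2 CPM of the members of the interferon response list and the cholesterol synthesis list, minus the mean of the Normal libraries, by class, with 1 point per library and the mean and SD of each group. In the endothelium the interferon list lies at 1.36, 1.18 and 0.14 in CKD, and in each of the 9 classes called 2 of 3 CKD libraries lie above every Normal library.

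Genes of cholesterol synthesis were lower in CKD in 5 of 8 classes. In the distal convoluted tubule 21 of 23 members were lower, with a median log2 fold of −0.67 (camera adjusted p = 9.36e-06), and in podocytes 6 of 6 at −0.62 (0.000861). They were lower in the endothelium, 9 of 12 at −0.40 (0.0146), in connecting tubule or principal cells 18 of 23 at −0.36 (0.000861) and in the thick ascending limb 15 of 22 at −0.27 (0.00088). All calls were lost with an estimated correlation, at adjusted p = 0.753, 0.729, 0.729, 0.759 and 0.729 with an estimated correlation in the same order. LSS, which closes the sterol ring, stood at 103, 83.5 and 179 CPM in the CKD distal convoluted tubule against 245, 237 and 241 CPM in Normal (log2 fold −0.99 ± 0.26, edgeR adjusted p = 0.595). The level of the list lay apart from every Normal library in all 3 CKD libraries in podocytes and the endothelium alone. In the other 3 classes CKD 3 went against the call. Its level was 0.21 above the Normal mean on the log2 scale in connecting tubule or principal cells, above every Normal library, against −0.55 and −0.76 in CKD 1 and CKD 2. In the distal convoluted tubule it was 0.31 against −0.91 and −0.87, above Normal 1 and Normal 3, and in the thick ascending limb 0.04 against −0.51 and −0.58. IDI1, an isomerase of the isoprenoid steps of the pathway, had −1.14 ± 0.37 in the thick ascending limb. SREBF2, its transcription factor, had −0.74 ± 0.22 in connecting tubule or principal cells. The adjusted p values were 1 and 0.635, and for these genes every CKD library lay below every Normal one. The calls in podocytes and the thick ascending limb held whichever library was left out, though the latter was lost with CKD 2 and Normal 1 both left out (adjusted p = 0.286). In the other classes it was lost without Normal 2 in the distal convoluted tubule (adjusted p = 0.0847), the endothelium (0.0847) and connecting tubule or principal cells (0.0548), and without CKD 2 in the endothelium (0.104) and connecting tubule or principal cells (0.229).

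In the endothelium the list of inflammation and NF-kB genes was lower in CKD, with 15 of 17 members down and a median log2 fold of −0.38 (camera adjusted p = 0.000322; adjusted p = 0.729 with an estimated correlation). The leukocyte adhesion molecules ICAM1 and VCAM1 stood at 71.4, 101 and 101 CPM against 226, 171 and 252 CPM and at 19.3, 26.6 and 48.5 CPM against 49.7, 104 and 52.2 CPM, with log2 folds of −1.24 ± 0.22 and −1.17 ± 0.40. Adjusted over the list alone 1 member fell. Genes of lipid uptake, storage and efflux were higher, 15 of 19 at a median of 0.41 (adjusted p = 0.00622; 0.729 with an estimated correlation). Among them were the cholesterol exporters ABCG1 (1.12 ± 0.42) and ABCA1 (0.64 ± 0.26). Angiogenesis and endothelial genes were higher, 19 of 24 at 0.24 (adjusted p = 0.00122; 0.729 with an estimated correlation), with the VEGF receptor KDR at 0.86 ± 0.31, its co-receptor NRP1 at 0.74 ± 0.26, ESM1, a secreted proteoglycan of endothelium, at 1.82 ± 0.51 and VWF, the platelet-binding factor, at 0.78 ± 0.24. Tubule injury genes were lower, 11 of 13 at −0.43 (adjusted p = 0.012; 0.729 with an estimated correlation), among them the phosphoprotein SPP1 at −1.85 ± 0.56. This list was drawn up for tubules and shares members such as VCAM1 with the inflammation list. RNA of tubule cells as the source of these counts was not tested. None of the 9 genes passed over all genes. All of these list calls held whichever library was left out except angiogenesis, which was lost without Normal 1 (adjusted p = 0.112). Leaving out both CKD 2 and Normal 1, the calls of lipid (0.075), angiogenesis (0.0887) and tubule injury genes (0.054) were lost. At equal depth that of tubule injury was lost (0.0868).

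In the proximal tubule 17 of 23 early response and heat shock genes were higher, at a median log2 fold of 0.67 (camera adjusted p = 0.0246; 0.857 with an estimated correlation). This call was lost without CKD 1 (adjusted p = 0.157), CKD 3 (0.135), Normal 2 (0.31) or Normal 3 (0.137). Oxidative stress and NRF2 genes were higher, 22 of 27 at 0.36 (adjusted p = 0.0172; 0.753 with an estimated correlation), with the superoxide dismutase SOD1 at 0.68 ± 0.21 and the exporter ABCC2 at 0.54 ± 0.16, but not without CKD 2 (adjusted p = 0.288) or Normal 2 (0.2). Genes of p53 and cell cycle arrest were higher, 14 of 19 at 0.22 (adjusted p = 0.0172; 0.729 with an estimated correlation), with the cell cycle inhibitor CDKN1A at 1.63 ± 0.66 and the stress-induced cytokine GDF15 at 1.27 ± 0.45, both under 3 CPM, but not without CKD 2 (adjusted p = 0.0603) or Normal 2 (0.0782). Genes of distal tubule and collecting duct transport were lower, 23 of 30 at −0.40 (adjusted p = 0.00908; 0.729 with an estimated correlation), but not without Normal 1 (adjusted p = 0.481). For the distal tubule and collecting duct list 0 of the 3 CKD libraries lay below every Normal one. It was drawn up for other segments, and RNA of those segments as the source of these counts was not tested. None of the 4 named genes passed over all genes. Lipid uptake, storage and efflux genes were not called, with 18 of 25 higher at 0.25 (adjusted p = 0.0532). Most nuclei of this class lay in clusters that came mainly from 1 library, as above.

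In podocytes 10 of 10 mitochondrion-encoded genes were higher in CKD, at a median log2 fold of 1.10 (camera adjusted p = 6.39e-10; 0.729 with an estimated correlation), and 9 rose adjusted over the list alone. ATP6, an ATP synthase subunit, stood at 703, 1227 and 686 CPM against 304, 388 and 210 CPM (log2 fold 1.53 ± 0.30). The same list was lower in 13 of 13 genes of the thick ascending limb, at −0.40 (adjusted p = 0.0012; 0.753 with an estimated correlation), where the call was lost without CKD 2 (adjusted p = 0.284) or Normal 1 (0.181). It was lower in 12 of 12 genes of intercalated cells, at −0.36 (adjusted p = 0.0196; 0.849 with an estimated correlation), where it was lost without CKD 2 (adjusted p = 0.288), CKD 3 (0.273) or Normal 1 (0.654) or at equal depth (0.113). In both classes CKD 1 lay above Normal 2 and Normal 3, at 0.18 above the Normal mean on the log2 scale in the thick ascending limb and 0.27 in intercalated cells, where CKD 2 and CKD 3 lay at −0.96 and −0.55 and at −0.84 and −0.77. CKD 1 had the highest median share of mitochondrion-encoded UMIs of the 6 libraries, at 0.475%. These genes are encoded outside the nucleus, so their counts in nuclei are of RNA carried along with them. Whether the amount carried along differed between groups in these classes was not tested. Genes of oxidative phosphorylation were higher in 4 of 12 classes, with a median of 0.35 in the distal convoluted tubule (55 of 60, adjusted p = 1.87e-09), 0.42 in podocytes (33 of 38, 0.00088), 0.23 in the endothelium (49 of 59, 0.000105) and 0.19 in connecting tubule or principal cells (54 of 64, 0.000758). With an estimated correlation the adjusted p was 0.729, 0.729, 0.729 and 0.791. It was lost in podocytes without CKD 2 (adjusted p = 0.284) or at equal depth (0.165) and in connecting tubule or principal cells without CKD 1 (0.313).

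Cytosolic ribosomal protein genes were higher in 11 of 11 classes, from a median of 0.13 in the thick ascending limb (44 of 61, adjusted p = 0.0353) to 0.71 in podocytes (50 of 52, 3.98e-09), with adjusted p values from 0.729 to 0.862 with an estimated correlation. The proximal tubule had 56 of 61 higher, at 0.23 (adjusted p = 7.95e-06), with RPS29, of the small subunit, at 0.81 ± 0.20 (edgeR adjusted p = 0.544; higher in 3 of 3 CKD libraries). The call was lost in the thick ascending limb without CKD 2 (adjusted p = 0.177), CKD 3 (0.0764), Normal 1 (0.111) or Normal 3 (0.251), in fibroblasts without CKD 2 (0.192), CKD 3 (0.132) or Normal 2 (0.796) and in cluster 32 without CKD 3 (0.843), Normal 1 (0.428) or Normal 2 (0.114). It was lost in the T or NK lymphocyte class without CKD 1 (0.116), CKD 2 (0.0636) or Normal 2 (0.795) and in intercalated cells without CKD 1 (0.122). With CKD 2 and Normal 1 both left out it was also lost in podocytes (0.379) and the endothelium (0.365), and at equal depth in parietal epithelium (0.329) and fibroblasts (0.0767). In the level of the list, 0 of 3 CKD libraries lay above every Normal one in fibroblasts and 1 in cluster 32. All 3 did in the proximal tubule, thick ascending limb, distal convoluted tubule and connecting tubule or principal cells, and 2 in the other classes.

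Proximal tubule transport genes were lower in intercalated cells, 23 of 28 at a median log2 fold of −0.71 (camera adjusted p = 6.97e-05), and in the distal convoluted tubule, 18 of 25 at −0.58 (0.000861). They were lower in connecting tubule or principal cells, 23 of 30 at −0.27 (0.0122), and in parietal epithelium, 14 of 17 at −0.27 (0.0041). The adjusted p was 0.729, 0.753, 0.753 and 0.729 with an estimated correlation. The endocytic receptor CUBN stood at 191, 221 and 231 CPM in CKD intercalated cells against 671, 394 and 456 CPM (log2 fold −1.24 ± 0.25), and LRP2, its partner, at 97.5, 80.1 and 81.7 CPM against 327, 128 and 138 CPM in the distal convoluted tubule (−1.17 ± 0.33). These cells are not known to use these carriers, and the share of UMIs from proximal tubule markers moved with the list. Most of these markers belong to the list, so the share follows it by construction and does not test the source of these counts. The share was 0.0962 ± 0.00882% in CKD against 0.176 ± 0.0858% in Normal intercalated cells (SD, n = 3; exact permutation p = 0.1, the smallest possible). It was 0.0991 ± 0.00759% against 0.176 ± 0.0945% in the distal convoluted tubule (SD, n = 3; exact permutation p = 0.2). All 4 calls were lost without Normal 1, at adjusted p values of 0.166, 0.428, 0.671 and 0.213. The call was also lost without CKD 2 in connecting tubule or principal cells (0.0603) and in parietal epithelium (0.0817). The list was higher in the T or NK lymphocyte class, 27 of 32 at 0.44 (adjusted p = 1.30e-07), and in cluster 32, 22 of 26 at 0.41 (0.000188), both at 0.729 with an estimated correlation. The call in cluster 32 was lost with CKD 2 and Normal 1 both left out (0.0728).

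Among the other cells, fibroblasts had higher angiogenesis and endothelial genes, 12 of 14 at a median log2 fold of 0.54 (camera adjusted p = 0.00182; 0.729 with an estimated correlation), whichever library was left out. Their early response genes were lower, 5 of 7 at −0.67 (adjusted p = 0.0122; 0.729 with an estimated correlation), with the immediate early factor EGR1 at −1.80 ± 0.64, but not without CKD 1 (adjusted p = 0.0597), CKD 2 (0.192), Normal 1 (0.459) or Normal 3 (0.0577). Cluster 32 had lower inflammation and NF-kB genes, 8 of 9 at −1.15 (adjusted p = 0.000322; 0.729 with an estimated correlation), whichever library was left out, and 5 fell adjusted over the list alone. The groups overlapped in the level of the list, with CKD at −0.86, −0.41 and −0.65 from the Normal mean on the log2 scale and Normal 1 among them at −0.71, against 0.53 and 0.18 in Normal 2 and Normal 3. Markers of immune cells also had a median log2 fold of −0.46 in this cluster (12 measured). Its share of UMIs from proximal tubule markers was 1.37 ± 0.0860% in CKD against 0.979 ± 0.363% in Normal (SD, n = 3, exact permutation p = 0.2). The fall of the list was not tested apart from these. NFKBIA, the inhibitor induced by NF-kB itself, stood in cluster 32 at 49.1, 46.5 and 17.4 CPM against 113, 121 and 139 CPM. In intercalated cells the same list was higher, 10 of 13 at 0.41 (adjusted p = 0.0226; 0.729 with an estimated correlation), but not without CKD 1 (adjusted p = 0.271), CKD 3 (0.0788) or Normal 1 (0.671). Renin-angiotensin-aldosterone genes were lower there, 9 of 10 at −0.46 (adjusted p = 0.00672; 0.729 with an estimated correlation), whichever library was left out but not with CKD 2 and Normal 1 both left out (0.0656).

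Fatty acid oxidation genes were higher in cluster 32, 18 of 22 at a median log2 fold of 0.42 (camera adjusted p = 0.00348), and in the T or NK lymphocyte class, 21 of 28 at 0.38 (0.00783). They were higher in podocytes too, 19 of 23 at 0.43 (0.0294). With an estimated correlation the adjusted p was 0.729, 0.729 and 0.849. The call was lost in the T or NK lymphocyte class without Normal 2 (adjusted p = 0.136) and in podocytes without CKD 2 (0.801), Normal 2 (0.106) or Normal 3 (0.191) or at equal depth (0.0624). The share of UMIs from proximal tubule markers was also higher in CKD in the T or NK lymphocyte class, as given above. It stood at 1.37 ± 0.0860% against 0.979 ± 0.363% in cluster 32 (SD, n = 3; exact permutation p = 0.2). The proximal tubule transport list, which holds most of those markers, was higher in both. In podocytes that share was 0.459% in CKD 2 and between 0.0917% and 0.173% in the other libraries. Glycolysis genes were higher in the distal convoluted tubule, 13 of 14 at 0.23 (adjusted p = 0.0314), with the glycolytic enzyme ENO1 at 0.68 ± 0.21, and in the endothelium, 13 of 15 at 0.22 (0.0189), both at an adjusted p of 0.729 with an estimated correlation. The first was lost without CKD 1 (0.0675), CKD 2 (0.146), Normal 2 (0.174) or Normal 3 (0.191) or at equal depth (0.123), the second without CKD 2 (0.0603), Normal 2 (0.0866) or Normal 3 (0.0768) or at equal depth (0.231). Gluconeogenesis genes were lower in intercalated cells, 9 of 13 at −0.26 (adjusted p = 0.0419; 0.753 with an estimated correlation), with G6PC1, the glucose-releasing phosphatase, at −1.67 ± 0.50, but not without CKD 2 (0.174), CKD 3 (0.301) or Normal 1 (0.547). The share of proximal tubule markers was lower in CKD in these cells too, as given above, and stood highest in Normal 1, at 0.275%, as did the level of this list. Oxidative stress and NRF2 genes were higher in the T or NK lymphocyte class, 17 of 21 at 0.30 (adjusted p = 0.0103; 0.729 with an estimated correlation), but not without CKD 2 (0.37), Normal 2 (0.0581) or Normal 3 (0.0738) or at equal depth (0.0637). They were also higher in podocytes, 16 of 18 at 0.35 (adjusted p = 0.0348; 0.729 with an estimated correlation), but not without CKD 2 (0.72), Normal 1 (0.0806), Normal 2 (0.0792) or Normal 3 (0.0507) or at equal depth (0.0702).

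Antigen presentation genes were higher in the endothelium, 12 of 13 at a median log2 fold of 0.28 (camera adjusted p = 0.0349; 0.729 with an estimated correlation), but not without CKD 1 (0.116), CKD 2 (0.192), Normal 1 (0.247) or Normal 2 (0.0548). Genes of the podocyte slit diaphragm were lower there, 11 of 13 at −0.34 (adjusted p = 0.0189; 0.729 with an estimated correlation), but not without CKD 1 (0.102), CKD 2 (0.236) or Normal 1 (0.545). Smooth muscle genes were lower in the distal convoluted tubule, 5 of 6 at −0.25 (adjusted p = 0.0436; 0.729 with an estimated correlation), but not without CKD 2 (0.0808), CKD 3 (0.168), Normal 2 (0.0679) or Normal 3 (0.121). The actin-binding CALD1 had −2.17 ± 0.44 there, at an edgeR adjusted p of 0.359 over all genes, and 1 member fell adjusted over the list alone. Genes of distal tubule and collecting duct transport were lower outside the tubule too, in the endothelium, 15 of 20 at −0.37 (adjusted p = 0.0189), in mural cells, 11 of 15 at −0.30 (0.00945), and in parietal epithelium, 14 of 16 at −0.22 (0.0246). With an estimated correlation the adjusted p was 0.799, 0.729 and 0.729. The call was lost in the endothelium without Normal 1 (0.585) or at equal depth (0.135), in mural cells without CKD 1 (0.0533), CKD 2 (0.333) or Normal 2 (0.0702), and in parietal epithelium without CKD 2 (0.0603) or Normal 1 (0.305) or at equal depth (0.0515). The share of UMIs from proximal tubule markers was 0.219 ± 0.0638% in CKD against 0.317 ± 0.196% in Normal endothelium (SD, n = 3; exact permutation p = 0.6) and 0.236 ± 0.0664% against 0.331 ± 0.116% in parietal epithelium (p = 0.4), highest in Normal 1 in both, at 0.544% and 0.462%. In mural cells the level of the list was 0.34 above the Normal mean on the log2 scale in CKD 3, above every Normal library, against −0.70 and −0.97 in CKD 1 and CKD 2.

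No class was called for genes of fibrosis, and cluster 36, which had fibroblast markers, was not tested. Of the extracellular matrix and fibrosis list 10 of 33 members were higher in the proximal tubule, at a median log2 fold of −0.22 (camera adjusted p = 0.112), and 11 of 27 in fibroblasts, at −0.11 (adjusted p = 0.362). In fibroblasts the collagen COL1A1 had a log2 fold of 0.46 ± 0.52, COL3A1 −0.62 ± 0.38 and FN1 −1.48 ± 0.38, with edgeR adjusted p values of 0.998, 0.998 and 0.933 and FN1 alone without overlap between groups. COL1A1 had −0.10 without CKD 3, and COL3A1 0.09 in classes by marker score. Camera also called 0 of 12 classes for the TGF-beta pathway (lowest adjusted p = 0.169, connecting tubule or principal cells), 0 of 12 for the hypoxia response (0.197, proximal tubule), 0 of 11 for the unfolded protein response (0.297, cluster 32), 0 of 11 for regulated cell death (0.131, parietal epithelium) and 0 of 6 for proliferation (0.0945, connecting tubule or principal cells). The same 6 lists gave 0 calls with an estimated correlation and by fry, as all lists did.

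The last comparison asked whether the effect of CKD differed between the proximal tubule and the thick ascending limb. EdgeR called 0 of 18631 genes for the interaction, with 1108 at an unadjusted p under 0.05, and DESeq2 called 24. Without Normal 1 edgeR called 7 and without Normal 2 it called 3. Simulated 4-fold differences were recovered at 67.5%, and smaller differences were not simulated.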

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

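Tests chosen after the result was seen were those of the interaction of the proximal tubule with the podocyte and the distal convoluted tubule, and those of podocytes and of each class apart for TAFA2.

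TAFA2 fell in the proximal tubule by more than its folds in the podocyte and the distal convoluted tubule. For the thick ascending limb, the planned comparison, the difference of −5.42 ± 0.63 (SE) did not pass (edgeR adjusted p = 0.0606). The log2 fold in the proximal tubule minus that in the podocyte was −8.53 ± 0.57 (SE; edgeR adjusted p = 1.03e-05), with every CKD library lower in the first and higher in the second class, and minus that in the distal convoluted tubule −6.18 ± 0.71 (adjusted p = 0.0145). For ADAM12 the log2 fold in the proximal tubule minus that in the distal convoluted tubule was 5.14 ± 0.70 (adjusted p = 0.0246), with every CKD library lower in the latter. Scaled to all UMIs, ADAM12 stood in the proximal tubule at 2.84, 1.53 and 3.02 CPM in CKD against 7.90, 2.87 and 3.31 in Normal. TAFA2 had 18, 13 and 0 UMIs in the CKD distal convoluted tubule against 9, 18 and 14 in Normal. Each of these comparisons thus had 1 class at a low level.

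The counts of TAFA2 outside the proximal tubule were set against a technical explanation, RNA of proximal tubule nuclei. This test does not bear on the fall within the proximal tubule itself. RNA of proximal tubule nuclei was argued against as the source of the counts in podocytes of Normal libraries, with 254 TAFA2 UMIs per 1000 LRP2 UMIs against 45.8 in the proximal tubule. For the other classes, at 54.9 together, it stays open: 6 of 11 lay within 1.5 times of the proximal tubule, and cycling cells (78.7), fibroblasts (76.0), mural cells (74.1), the distal convoluted tubule (71.7) and parietal epithelium (10.99) did not. A variant shared by the pigs of a group stays open and was not tested: of the 7 genes called, 5 unnamed ones lay in 1 run of the annotation order, 245 to 251 positions from TAFA2. An effect of the disease model also stays open and was not tested apart from parentage.

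CKD 2, a library of all main comparisons, carried Y-linked RNA. Whether this pig was male is not settled here, and sex was not a term in any test. If it was male, sex differed between the groups. The levels in CKD 2 were 108 CPM of ZFY, 36.6 CPM of KDM5D and 49.1 CPM of EIF1AY, from 5446, 1843 and 2475 UMIs. In the other libraries ZFY was at most 0.983 CPM. A Y-linked UMI was seen in 55.5% of the nuclei of CKD 2, at a median of 4875 UMIs per nucleus, and in 0.581% of those of Normal 3, at 4294. KDM6A, which lies on the X chromosome, was at 205 CPM in CKD 2 and between 366 and 422 CPM in the others.

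Cluster 36, which stayed unnamed and entered no test of genes, held a mean of 0.296 ± 0.101% of CKD nuclei and 0.0940 ± 0.0418% of Normal nuclei (SD, n = 3 per group; exact permutation p = 0.1, the smallest possible). Every CKD library lay above every Normal one, with 95 nuclei in all. The cluster had 8 of 10 fibroblast markers, and ACTA2 and MYH11, markers of mural cells, were among its leading genes. It was counted neither with the fibroblasts nor with the mural cells.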

How the results depend on the processing

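Alternatives chosen after the data were seen were Scrublet's automatic calls, Leiden seed 2 and leaving out CKD 2 and Normal 1 together. No paired analysis was possible because replicate numbers were given in accession order and pair no samples. Of simulated 2-fold changes 5.80% were recovered in the proximal tubule and 27.7% in fibroblasts, with depth not varied. At equal depth edgeR called 8 genes in all nuclei and 7 in the proximal tubule, and 13 of the 60 list calls that could be tested were lost; the other 5 had under 5 measured members. The T or NK lymphocyte class and cluster 32 had no counterpart at Leiden resolution 2 or with seed 2, so these gave no value for them. In the other classes and in the interaction both clusterings gave the same gene counts as the main clustering, and camera called 57 and 59 lists.

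DESeq2 called 116 genes in all nuclei, 125 in the proximal tubule, 44 in connecting tubule or principal cells, 29 in intercalated cells, 19 in the distal convoluted tubule, 15 in the T or NK lymphocyte class, 12 in the endothelium, 12 in the thick ascending limb, 3 in podocytes, 2 in fibroblasts, 2 in cluster 32 and 24 in the interaction. With no filter on low counts edgeR called 13 in the proximal tubule, 197 in intercalated cells, 196 in the endothelium, 168 in podocytes, 159 in the distal convoluted tubule, 150 in connecting tubule or principal cells, 94 in the thick ascending limb, 86 in the T or NK lymphocyte class, 64 in fibroblasts, 53 in parietal epithelium, 47 in cluster 32, 30 in mural cells and 237 in the interaction. Leaving out both CKD 2 and Normal 1 gave 1 call in all nuclei, the proximal tubule, cluster 32, intercalated cells and podocytes each, 6 in the distal convoluted tubule and 2 in the interaction, and camera called 30 lists. At equal depth the counts were 1 in parietal epithelium and 1 in the interaction. In the T or NK lymphocyte class edgeR called 1 with adjustment over all classes, 8 with doublets kept and 5 at 2% mitochondrion-encoded UMIs, and 0 at equal depth, with equal nuclei and by marker score, with 209, 409 and 365 genes at an unadjusted p under 0.05. Marker score gave 12 in the proximal tubule and 2 in parietal epithelium. Fibroblasts gave 5 with doublets kept and 1 at 2% mitochondrion-encoded UMIs, and the interaction 2 with at least 800 genes and 1 at 2% mitochondrion-encoded UMIs. Camera with an estimated correlation and fry called 0 lists, with 12 and 34 at an unadjusted p under 0.05. The cause was not tested in any of these.

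With each library left out in turn, counts ranged from 0 to 18 in all nuclei, 0 to 16 in the proximal tubule, 1 to 7 in the distal convoluted tubule, 0 to 3 in the T or NK lymphocyte class, 0 to 3 in intercalated cells, 0 to 1 in cluster 32, podocytes and the thick ascending limb, 48 to 79 for lists and 0 to 7 in the interaction.
The log2 fold of shares ranged from −0.44 to 0.61 in the T or NK lymphocyte class, −0.0865 to 0.28 in connecting tubule or principal cells, −1.13 to 0.57 in cycling cells, −0.10 to 0.26 in fibroblasts, −0.0533 to 0.66 in lymphatic endothelium, −0.19 to 0.41 in mural cells, −0.0548 to 0.15 in parietal epithelium, −0.54 to 0.0135 in podocytes and −0.0710 to 0.00594 in the proximal tubule.

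By marker score the log2 fold of shares reversed to −0.41 in the T or NK lymphocyte class, −0.0821 in connecting tubule or principal cells, −0.31 in fibroblasts, −0.34 in lymphatic endothelium, −0.23 in mural cells, −0.25 in parietal epithelium and 0.24 in the proximal tubule. Leaving out both CKD 2 and Normal 1 it reversed to −0.19 in connecting tubule or principal cells, −0.19 in fibroblasts, 0.14 in podocytes and 0.0385 in the proximal tubule. At Leiden resolution 2 it reversed to 0.25 in cycling cells, 0.36 in the distal convoluted tubule, −0.0328 in fibroblasts, −0.0503 in mural cells and 0.0779 in the proximal tubule. In mural cells it reversed to −0.0410 with Leiden seed 2, −0.0144 with automatic doublet calls and −0.0414 at 2% mitochondrion-encoded UMIs, and in parietal epithelium to −0.0056 with a denominator outside the proximal tubule. The cause was not tested.

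In fibroblasts COL3A1 reversed to 0.0932 by marker score, and COL1A1 lay between −0.10 and 0.97 with each library left out.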

Other observations

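Of the tests below, those of depth for the cluster led by NOS1, except the share of nuclei with a NOS1 UMI after thinning, and those of the interferon response outside the endothelium and the thick ascending limb were chosen after the result was seen.

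Within the thick ascending limb, cluster 30 was larger in CKD. It was picked as the cluster of this class with the highest mean level of 3 chosen genes. These were NOS1, the neuronal nitric oxide synthase, PTGS2 and PAPPA2, a protease of insulin-like growth factor binding proteins. The first pair are known from the macula densa, the salt sensor beside the glomerulus. PAPPA2 and NOS1 were among the 10 leading genes of cluster 30 and PTGS2 was not, and PAPPA2 was also among those of cluster 8. Cluster 30 held 13.9, 14.8 and 11.2% of the thick ascending limb nuclei in CKD and 3.28, 4.29 and 4.25% in Normal (exact permutation p = 0.1, the smallest possible). NOS1 lies on chromosome 14 at 35112898 to 35299297 and PTGS2 on chromosome 9 at 127850164 to 127858866 of Sscrofa11.1. In the same class SPP1 stood at 74.1, 36.6 and 38.5 CPM against 14.1, 26.4 and 7.77 CPM and EGF, a growth factor of this segment, had a log2 fold of 0.66 ± 0.31, neither past the threshold.

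After clustering without the genes that differ between the groups, the lowest CKD share of the cluster was 8.74% and the highest Normal share 4.90%. Of its 298 nuclei 280 were from cluster 30, so most grouped without those genes. The cluster was again picked by its level of NOS1, PTGS2 and PAPPA2, which were among the genes left out and higher in CKD. That pick can favour CKD nuclei, so placement by such genes stays open. Depth of Normal 1 alone was argued against for cluster 30, as the highest share of the other Normal libraries was 4.29% and the lowest of CKD 11.2%. Lower depth of the Normal libraries as a group was argued against by clustering again after each nucleus was thinned to 1000 UMIs, where the cluster, with 298 of its 324 nuclei from cluster 30, held at least 9.81% in CKD and at most 4.41% in Normal. The same thinning left shares of nuclei with a UMI of 3.13 to 4.44% against 2.07 to 2.28% for NOS1, 1.28 to 2.18% against 0.526 to 0.862% for PTGS2 and 23.2 to 38.75% against 3.86 to 14.8% for PAPPA2. Unthinned, a UMI of these genes was seen in 8.58, 4.27 and 44.0% of CKD and 4.62, 1.32 and 17.9% of Normal nuclei of this class with at least 1000 UMIs, and in 1.13, 0.266 and 14.2% against 1.41, 0.199 and 9.42% in the proximal tubule, which should lack them, so a larger macula densa in CKD is a hypothesis found and tested on the same libraries.

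The interferon response in CKD was set against technical explanations. A single library was argued against in the endothelium, where the median log2 fold was at least 0.640 with each library left out, and in 3 other classes, but stays open in 5, among them the proximal tubule (0.224) and intercalated cells (0.169), both without CKD 2. Lower depth of Normal 1 was argued against in the endothelium by a median of 0.959 at equal depth and in 6 other classes, but stays open in intercalated cells, at 0.113, and in parietal epithelium, with 4 members measured. More RNA of immune cells was argued against in the thick ascending limb, with a median of −0.453 for 8 immune markers. It was also argued against in connecting tubule or principal cells (−0.454). In the proximal tubule (−0.125) it stays open, as the upper quartile of 0.229 was barely under the bound of 0.231. The bound was 0.5 times the median of the interferon list. It also stays open in the other 6 classes, with at most 4 markers measured and a median of up to 0.407, in parietal epithelium. These markers follow the amount of immune RNA and not the interferon genes within it. Those had a median log2 fold of 0.525 in cluster 32 and 0.0745 in the T or NK lymphocyte class. CKD 3 lay below the highest Normal library in each of the 9 classes called, so a response to the disease model and one to an infection or housing shared by CKD 1 and CKD 2 both stay open and were not tested.

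The 10 splits of the 6 libraries were too few for a share under 0.05. The real split called 10 genes in all nuclei, 7 in the proximal tubule, 3 in the distal convoluted tubule and 2 in the T or NK lymphocyte class, and the highest of the other splits called 1, 1, 0 and 1, so that in each 1 split, the real one, reached the real count. For lists the real split called 65, and 3 splits reached that count. CKD 1, CKD 2 and Normal 1 against the rest gave 66. CKD 1, CKD 2 and Normal 2 gave 67, the highest, and the lowest of the other splits gave 33. In the 9 classes with 0 calls by edgeR and in the interaction all 10 splits reached that count, with at most 1 call in another split; the counts at an unadjusted p under 0.05 and by DESeq2 stand in the results.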
